A study of Homo sapiens with 6 samples.

How the data were processed

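Total RNA of 6 LNCaP cultures, 3 controls and 3 treated with 100 nM DHT for 48 h, was extracted with a silica column kit, converted to biotin-labelled cRNA and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The authors deposited 1 table of signal intensities on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 summarises the probe pairs of a probe set into 1 signal after subtracting a mismatch or estimated background, so that dim probe sets are noisy and small values are not reliable. The mean of each deposited array after trimming 2% at both ends was 100.03, so the arrays had been scaled to a common level before deposition, and no further normalisation was applied. A common scale removes any change in the total amount of mRNA, and all fold changes are relative to the average transcript. Detection calls and scanner files were not used here. Samples were assigned to groups by their titles, and 0 columns of the table were left unused.

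Of 54675 probe sets, 62 are array controls and were left out of all tests. In the platform annotation given with the table, 41097 probe sets name 1 gene, 1801 name several and 11777 are unnamed here; no gene is named from a probe set with several. Symbols were looked up by gene identifier in a gene table of assembly GRCh38.p14, which matched 41043 of the single-gene probe sets, changed 0 symbols, and left 54 under the name in the annotation. No build is named in the sources used here, and no coordinates are given. The lowest 40% of probe sets by mean log2 signal over all 6 arrays were removed, at a signal of 17.3, leaving 32768 with a median signal of 76.3. Tests ran on log2(signal + 16), a scale that understates the fold change of dim genes, with limma (lmFit, and eBayes with an intensity trend, version 3.58.1 in R 4.3.3) and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. A gene was read from its brightest probe set that names it alone, with probe sets ending in _x_at, which are prone to cross-hybridisation, used only where no other passed. This gave 14269 genes, 7484 of them with 1 tested probe set. Adjusted p-values of genes are over genes, except where they are given over probe sets. Signals are given as mean ± SD over 3 arrays and fold changes with limma's standard error, whose median was 0.14.

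The 25 gene lists were written from textbook knowledge before the data were examined, as were the groups, the test, the naming rule and the alternatives apart from the spike scaling. They hold 574 entries, of which 456 were tested, 63 were below the limit on dim probe sets and 55 had no single-gene probe set and were not analysed here. Lists were tested with limma's camera at its preset correlation of 0.01, Benjamini-Hochberg adjusted over the 25 lists, and with an estimated correlation and with fry beside it. The estimated-correlation test also uses the 4 residual degrees of freedom of the fit, far fewer than the preset test. Its p-values can therefore rise even where the estimated correlation is near 0.01. Several lists share members. The named genes are the 12 largest rises and the 12 largest falls among genes that passed, with the 3 arrays of one group all above those of the other and the brighter group at or above the median tested signal; 6 androgen-related genes fixed in advance, of which 4 were tested and the others were not analysed here; and from each list the 4 tested members with the smallest adjusted p. Members beyond these (MYC, SEC61B, PLA2G2A, FASN, FADS2, NDRG1, STEAP4, AZGP1, FOXA1, AURKA, MKI67, CENPA, CHGA, SLC1A5, STS and ATP13A2) were chosen after their values were seen, to complete a small count or show the range of a list. The 3' to 5' ratios of the GAPDH and ACTB control probe sets and the mean signal of the control probe sets of each of 4 hybridisation spikes were compared by two-sided exact permutation tests, where 3 against 3 arrays cannot give a p below 0.1 (scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15).

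The alternatives were pseudocounts of 1 and 64, no limit on dim probe sets or a limit at 60%, quantile normalisation, equal array medians, the replicate number as a block, limma without the trend or with a robust fit, the mean of a gene's probe sets, and leaving out each array in turn. In data simulated at the real signals, with 200 changed probe sets and 3 arrays against 3, the fit called 8.20% of probe sets changed by 0.5 on the log2 scale, 63.9% of those changed by 1 and 87.7% of those changed by 2, with 4 of 98 calls false among 32768 tested. In the real data 3388 probe sets passed, and with so few simulated changes the Benjamini-Hochberg cut is stricter. The simulated noise was also independent between probe sets. These shares therefore do not carry over to the real comparison.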

Results

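The data describe the transcriptome of LNCaP cells, an established androgen-responsive line derived from a human prostate cancer metastasis. The cells were kept for 3 days in phenol red-free medium with 10% serum stripped of steroids by charcoal and dextran. One group of 3 cultures then received 100 nM dihydrotestosterone (DHT), the most potent natural androgen, for 48 h, and 3 further cultures served as controls. What the control cultures received in place of DHT is not given in the sources used here. Total RNA of each culture was hybridised to 1 Affymetrix expression array with 54675 probe sets. The signal was already scaled, with a mean of 100.03 on each array after trimming 2% at both ends. The median signal of an array was 27.6 ± 2.16 in the controls and 28.8 ± 1.10 with DHT (SD, n = 3 each). The labels call the arrays of a group biological replicates. They do not say whether the cultures were grown on separate days. The p-values therefore rest on the spread between these 3 cultures per group, whose number limits the precision. They also rest on variance that limma borrows from probe sets of similar signal. The fit had 4 residual degrees of freedom and a median total of 11.4. Across probe sets, which are not independent replicates, the arrays correlated at r = 0.973 to 0.978 within a group and at r = 0.958 to 0.966 between the groups. The first principal component held 38.8% of the variance and separated the groups.

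The comparison of DHT with control asked which transcripts change when androgen is returned to steroid-deprived prostate cancer cells. The largest rise was in KLK2, which encodes a secreted serine protease of the prostate. Its signal (probe set 209854_s_at) went from 109 ± 9.97 to 2082 ± 124 (SD, n = 3 each), a 19.2-fold rise, with a log2 fold change of 4.07 ± 0.09 (SE; limma adjusted p = 2.84e-10). TMPRSS2, a membrane-bound serine protease (211689_s_at), rose 6.78-fold from 304 ± 20.4 to 2064 ± 166. KLK3, which encodes prostate-specific antigen (204582_s_at), rose 4.11-fold from 2186 ± 261 to 8985 ± 441. The largest fall was in APP, the amyloid precursor protein (214953_s_at), whose signal went from 1991 ± 128 to 441 ± 41.1, a log2 fold change of -2.14 ± 0.09 (limma adjusted p = 1.27e-07).

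In total, 1834 of 14269 tested genes passed an adjusted p of 0.05 in limma, 991 of them higher with DHT and 843 lower. Of these, 144 differed at least 2-fold on the log2(signal + 16) scale, 98 higher and 46 lower (228 with a pseudocount of 1, 48 with one of 64 and 93 with the mean of a gene's probe sets), and 895 had an absolute log2 fold change under 0.5. At the level of probe sets, 3388 of 32768 passed, 1669 higher and 1719 lower. The 3 DHT arrays lay above all 3 control arrays for 2413 genes and below them for 2004, together 31.0% of the genes against 10% by chance. All directions are relative to the average transcript of an array. An alternative chosen after the data were seen scaled the arrays instead to the hybridisation spikes described further on. The median log2 fold change was then -0.53. With this scaling 104 genes passed as higher and 9141 as lower (1.12% of the calls higher, against 54.0% with the deposited scaling). The spike offset of an array was subtracted from log2(signal + 16), so every gene's fold change was lowered by the same amount. For dim genes that is more than scaling the signal itself would give. The spike-scaled values are therefore the main values minus a constant and no independent check. The same holds for list calls in camera gained or lost with spike scaling, since camera uses fold changes divided by their errors. With equal array medians 45.0% of the calls were higher, and 1168 genes passed without control replicate 3 and 1178 without DHT replicate 3. Without the intensity trend in limma's variance 671 genes passed, and of the genes named here as changed CEBPZOS, LINGO3, INSIG1, SQLE, ERN1, TRIB3, DDIT3, PHGDH, IGFBP2, UGT2B17, ACP3, KRT8, SRM, HOXB13, EP300, PIAS1, NCOA1, PKM, SDHC, UQCRC2, UQCRC1, UQCRB, NOLC1, BAX, IFIT1, OAS3, COL1A1, MYC, SEC61B, PLA2G2A, FADS2, SLC1A5 and ATP13A2 no longer did.

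Besides KLK2, TMPRSS2 and KLK3, the 12 largest rises included TRPM8, PMEPA1, SLC45A3, PSLNR and ELOVL7. TRPM8, a cation channel opened by cold, rose by 1.94 ± 0.21 on the log2 scale (SE), from a control signal of 12.8 that lay below the 17.3 used as the lower limit for a probe set's mean. PMEPA1, a membrane protein that restrains TGF-beta signalling, rose 3.95-fold from 161 ± 20.3 to 635 ± 87.5. SLC45A3, also called prostein, rose 2.99-fold from 351 ± 10.5 to 1048 ± 82.8. The long noncoding RNA PSLNR rose 4.91-fold, and ELOVL7, an elongase of long-chain fatty acids, rose 4.63-fold from 99.7 ± 4.62 to 461 ± 47.6. The remaining rises under the naming rule were CDCA8 (log2 fold change 1.69), a subunit of the chromosomal passenger complex, the orphan receptor GPR158 (1.60), the ephrin ligand EFNA5 (1.59) and the ubiquitin ligase NEURL1B (1.54). Different probe sets of a gene did not always move alike. The dimmest KLK2 probe set had a log2 fold change of 0.28 (adjusted p = 0.578 over probe sets), and KLK2 and KLK3 are close in sequence, so that their probe sets can share signal. A second TRPM8 probe set had 0.42 (adjusted p = 0.457). The 4 TMPRSS2 probe sets all passed, between 1.02 and 3.08.

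The next falls by the naming rule were led by MINK1, RAB5C, FKBP10 and ERGIC1. RAB5C, a small GTPase of early endosomes, dropped from a signal of 749 ± 65.1 to 211 ± 14.1 (log2 fold change -1.75 ± 0.09), and its other probe set had -1.35. ERGIC1, a protein that cycles between endoplasmic reticulum and Golgi, dropped from 2546 ± 97.7 to 861 ± 90.5 (-1.55 ± 0.08). FKBP10, a prolyl isomerase of the endoplasmic reticulum that acts on collagen, dropped from 385 ± 35.4 to 113 ± 18.5, and the recycling GTPase RAB11B from 338 ± 41.7 to 130 ± 23.5. The kinase MINK1 had -1.88, but its signal with DHT of 12.4 lay below the limit of 17.3, and its other probe sets had -0.93, -0.58 and -0.27. The other falls were CEBPZOS (-1.42), LINGO3 (-1.37), the nuclear matrix protein MATR3 (-1.34), ZFP92 (-1.31), SCAF1 (-1.29) and the transcriptional corepressor ATN1 (-1.28). SCAF1 was read from a probe set ending in _x_at, prone to cross-hybridisation. All 3 APP probe sets passed as lower, at -0.54, -1.08 and -2.14, a 4.52-fold difference in signal for the brightest. For the same arrays, the ratio of 3' to 5' signal of ACTB was 1.37 ± 0.05 in the controls and 1.77 ± 0.07 with DHT. MINK1 had -0.27 (adjusted p = 0.154) with the lowest 60% of probe sets left out, where another of its probe sets was read. CEBPZOS did not pass without control replicate 3 (-1.17, adjusted p = 0.0839), LINGO3 did not pass when any array except DHT replicate 1 was left out (adjusted p = 0.0516 to 0.0783), and neither passed without the filter on dim probe sets (adjusted p = 0.0522 and 0.0595).

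**Figure D1:**
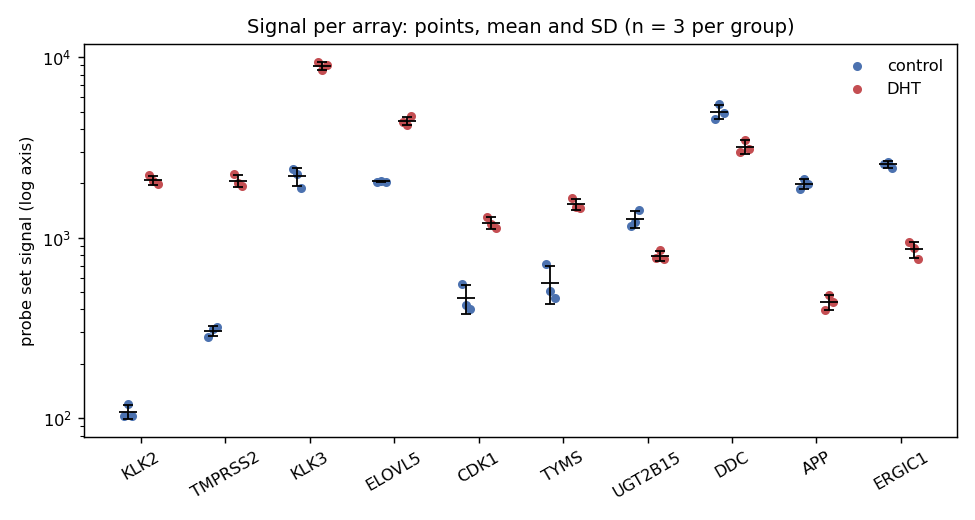
Signal of 10 named genes on each array, on a logarithmic axis, with controls in blue and DHT in red; bars give the mean and SD of 3 arrays. KLK2 went from 109 to 2082 and APP from 1991 to 441, and the 3 arrays of a group lay apart from those of the other group for each of the 10 genes.

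Nearly all tested mitotic genes rose. Of 34 tested members of the mitosis list, 31 rose and none fell, with a median log2 fold change of 0.99, and 33 rose when adjusted over the list alone. CDK1, the kinase that drives entry into mitosis, rose from a signal of 461 ± 83.0 to 1210 ± 87.9 (log2 fold change 1.37 ± 0.11). HMMR rose by 1.33 ± 0.14, MAD2L1 of the spindle checkpoint by 1.11 ± 0.11, and PRC1, which bundles microtubules of the central spindle, by 1.01 ± 0.11. The members that did not pass were AURKA (0.42), MKI67 (0.34) and CENPA (-0.17), though AURKA and MKI67 passed with the mean of their probe sets (0.66 each, adjusted p = 0.0137 and 0.00647). Of 39 tested DNA replication genes, 19 rose and none fell, with a median of 0.50, and 24 rose when adjusted over the list alone. TYMS, thymidylate synthase, rose 2.73-fold from 561 ± 135 to 1533 ± 112, RRM2 of ribonucleotide reductase rose 2.33-fold, and the replicative helicase subunit MCM2 rose by 0.83 ± 0.10. The preset-correlation camera test of limma gave an adjusted p of 2.42e-26 for mitosis and 2.91e-12 for DNA replication. With an estimated correlation the values were adjusted p = 0.190 for mitosis and adjusted p = 0.269 for DNA replication. With spike scaling the median was 0.44 for mitosis and -0.05 for DNA replication. At an unadjusted p under 0.05, limma gave 33 mitosis and 24 replication genes as higher and 0 as lower. These rises stood beside a GAPDH 3' to 5' ratio of 0.904 ± 0.044 in the controls and 1.06 ± 0.05 with DHT.

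The list of androgen-induced genes, drawn up from textbook knowledge and not from these arrays, had 29 tested members, of which 20 rose and 1 fell. Its median log2 fold change was 0.78, and 22 rose and 1 fell when adjusted over the list alone. AZGP1, a secreted zinc-binding glycoprotein, rose 2.61-fold from 189 ± 29.9 to 491 ± 45.1. FKBP5, a cochaperone of steroid receptors, rose 1.71-fold from 222 ± 8.53 to 379 ± 77.0 (0.72 ± 0.12), but its other probe sets had -0.03 and 0.24 and did not pass, and the mean over its probe sets was 0.31 (adjusted p = 0.147). The member that fell was PLA2G2A, a secreted phospholipase, at -0.42, and it did not pass without DHT replicate 1, DHT replicate 3 or control replicate 1 (adjusted p = 0.0537 to 0.059). NDRG1 (0.15) and STEAP4 (-0.12) did not pass. The camera adjusted p was 5.54e-20 for this list, with adjusted p = 0.0565 with an estimated correlation. With spike scaling the median was 0.22. Among 12 tested kallikreins, KLK2, KLK3 and KLK4 (0.58 ± 0.10) rose, also when adjusted over the list alone, and the other 9 did not pass, KLK7 among them at 0.76 (adjusted p = 0.194). The kallikrein list had an adjusted p of 0.00458 in camera and adjusted p = 0.190 with an estimated correlation, and its median was 0.17, or -0.38 with spike scaling. Its 3 risen members are also in the androgen-induced list.

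Of 15 tested genes on the androgen-repressed list, 8 fell and 2 rose, with a median log2 fold change of -0.31, and 8 fell and 4 rose when adjusted over the list alone. IGFBP2, a binding protein of insulin-like growth factors, went from 892 ± 109 to 515 ± 109 (-0.79 ± 0.14). DDC, which decarboxylates aromatic amino acids, went from 4989 ± 461 to 3188 ± 270 (-0.64 ± 0.09). UGT2B15, UGT2B17 and UGT2B28, enzymes that glucuronidate androgens, fell at -0.66, -0.42 and -0.71. They are related in sequence, and UGT2B15 and UGT2B28 were read from probe sets marked as prone to cross-hybridisation. The members that rose were the transcription factor MYC (0.60 ± 0.12) and SLITRK3 (0.57 ± 0.09), against the direction in the list's name. With no filter on dim probe sets UGT2B15 was read from a dim one, at -0.04 (adjusted p = 0.966). Camera gave an adjusted p of 0.00831, and adjusted p = 0.487 with an estimated correlation, and fry 0.0583. Of 14 tested genes of androgen synthesis and inactivation, the same UGT2B genes fell and 2 rose, also when adjusted over the list alone, with a camera adjusted p of 0.706. The risen genes were steroid sulfatase STS (0.53) and the peroxisomal enzyme HSD17B4 (0.52). With spike scaling these medians were -0.86 and -0.62. STS did not pass without DHT replicate 2 (adjusted p = 0.056) or with the mean of its probe sets (0.31, adjusted p = 0.122).

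Of 21 tested genes of cholesterol synthesis and uptake, 8 rose and none fell (9 rose when adjusted over the list alone; at an unadjusted p under 0.05 limma gave 11 higher and 0 lower), with a median of 0.23. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose from 541 ± 68.7 to 850 ± 145, squalene epoxidase SQLE from 426 ± 42.2 to 613 ± 79.8, and SC5D from 1020 ± 46.0 to 1441 ± 69.3. The other INSIG1 probe sets had 0.93 and 0.05 (limma adjusted p = 0.000218 and 0.844 over probe sets). HMGCS1 had 0.51 ± 0.11 in the probe set read here and -0.64 in a dimmer one (adjusted p = 0.00666 over probe sets), and -0.06 in their mean. With such means SQLE did not pass either (adjusted p = 0.0728). The list had a camera adjusted p of 0.0013, and adjusted p = 0.416 with an estimated correlation. Its median was -0.33 with spike scaling, where the list did not pass in camera (adjusted p = 0.121). Fatty acid synthesis genes went both ways. Of 19 tested, 5 rose and 4 fell (6 and 4 when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.433) but passed in fry (adjusted p = 0.0175), which does not compare it with other genes. ELOVL5 rose 2.16-fold from 2050 ± 10.3 to 4434 ± 239, and ACACA, the rate-limiting carboxylase of the pathway, rose by 0.74 ± 0.08. The citrate carrier SLC25A1 (-0.63 ± 0.09) and the desaturase FADS2 (-0.67 ± 0.14) fell, and fatty acid synthase FASN had -0.26 (adjusted p = 0.252; 0.0198 without DHT replicate 1).

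In the endoplasmic reticulum, 9 of 25 tested chaperone and quality control genes rose and 1 fell, with a median of 0.17 and 10 higher and 3 lower when adjusted over the list alone. MANF rose from 600 ± 76.8 to 975 ± 104, the stress sensor ERN1 from 213 ± 12.5 to 345 ± 63.4 and the cochaperone DNAJB9 from 353 ± 27.0 to 523 ± 28.6. The other DNAJB9 probe sets had 0.52 and 0.10 (limma adjusted p = 0.0193 and 0.638 over probe sets). The translocon subunits split, with SEC61A1 at 0.48 ± 0.07 and SEC61B at -0.47 ± 0.13. Camera gave an adjusted p of 0.00321, and adjusted p = 0.190 with an estimated correlation, and with spike scaling the median was -0.38 and the list did not pass (adjusted p = 0.780). SEC61B did not pass without DHT replicate 1, DHT replicate 3, control replicate 1 or control replicate 3 (adjusted p = 0.0583 to 0.128), without the filter on dim probe sets (adjusted p = 0.0843) or with the mean of its probe sets (-0.22, adjusted p = 0.244). In 31 tested genes of transport from endoplasmic reticulum to Golgi, 4 rose and 2 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.496). SAR1A, a GTPase of coat assembly, rose by 0.62 ± 0.08 and the cargo receptor LMAN1 by 0.45 ± 0.07, while the coat subunit COPG2 dropped from 164 ± 2.25 to 58.9 ± 7.84 (-1.27 ± 0.13). Of 23 ATF4 targets and amino acid synthesis genes, 4 rose and 2 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.496, and 0.024 with spike scaling). TRIB3 (0.53) and DDIT3 (0.48) rose, and the glutamine carrier SLC1A5 (-0.69) and serine synthesis enzyme PHGDH (-0.39) fell. With the mean of a gene's probe sets, ERN1, SEC61A1, SAR1A and TRIB3 did not pass (adjusted p = 0.0609, 0.065, 0.0509 and 0.586). DDIT3 did not pass without DHT replicate 1 (adjusted p = 0.0583) or control replicate 3 (adjusted p = 0.0598), nor SLC1A5 without DHT replicate 1, DHT replicate 3, control replicate 1 or control replicate 3 (adjusted p = 0.0543 to 0.0668).

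Luminal prostate markers had 13 tested members, of which KLK3, CLDN8 (0.72 ± 0.10) and ACP3, prostatic acid phosphatase (1324 ± 200 to 2106 ± 248), rose, and keratin KRT8 fell (-0.43 ± 0.08), with 6 higher and 1 lower when adjusted over the list alone. KRT8 was read from a probe set marked as prone to cross-hybridisation. The list median was 0.23, with a camera adjusted p of 0.00726 and adjusted p = 0.190 with an estimated correlation. It was -0.32 with spike scaling. Other lists did not pass in camera. Among 14 polyamine genes, ARG2 (2.04-fold), AMD1 (1.63-fold) and SAT1 (1.60-fold) rose, and spermidine synthase SRM (-0.49) and ATP13A2 (-0.58) fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.365, fry 0.0175). In the list of metallothioneins and zinc transport, 3 of 16 rose and 2 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.758), with the zinc importer SLC39A8 up 1.75-fold and SLC39A7, which releases zinc from the endoplasmic reticulum, at -1.05 ± 0.10. Of 15 androgen receptor cofactors and prostate transcription factors, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.706). HOXB13 (-0.37) and EP300 (-0.44) were among the falls, and FOXA1 had -0.05. PIAS1 (-0.46) also fell, but with an array left out it passed only without control replicate 2. NCOA1 (0.40) rose, but not without DHT replicate 2, DHT replicate 3, control replicate 1 or control replicate 2 (adjusted p = 0.0574 to 0.0999). Another NCOA1 probe set had -0.66 (adjusted p = 0.00909 over probe sets). With the mean of their probe sets PIAS1 had -0.09 and NCOA1 0.05 (adjusted p = 0.640 and 0.763). ATP13A2 (adjusted p = 0.0475) passed in the fits with an array left out only without control replicate 2, and did not pass with quantile normalisation, equal medians, a pseudocount of 1, no filter on dim probe sets or the mean of its probe sets (adjusted p = 0.0527 to 0.0893). SRM did not pass without control replicate 1 (adjusted p = 0.0512), EP300 without control replicate 3 (adjusted p = 0.0516) and HOXB13 without DHT replicate 1, DHT replicate 3 or control replicate 3 (adjusted p = 0.069 to 0.087).

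Of 21 glycolysis genes, PKM fell (-0.44) and none rose, and of 25 mitochondrial respiration genes 4 fell and none rose, SDHC at -0.39 and UQCRC2 at -0.27 among them. The counts were the same when adjusted over the list alone, and the camera adjusted p was 0.648 and 0.190. The respiration list passed in camera under quantile normalisation (adjusted p = 0.025) and without control replicate 3 (adjusted p = 0.016). It also passed with spike scaling (adjusted p = 2.72e-05), although its median kept its place relative to all genes. The list median was -0.04 against 0.02 for all genes in the main fit, and -0.60 against -0.53 with spike scaling. That pass is therefore no evidence of a further shift. At an unadjusted p under 0.05, limma gave 3 glycolysis genes and 2 respiration genes as higher. The glycolysis gene GAPDH passed as higher without control replicate 2 (0.44, adjusted p = 0.0039). PFKP of the same list passed as lower without control replicate 3 (-0.43, adjusted p = 0.046). NOLC1 (0.23) rose of 21 ribosome biogenesis genes, and 0 when adjusted over the list alone (4 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 0.468). BAX (-0.56) fell of 17 p53 targets, CDKN1A having -0.15, and IFIT1 (0.98) and OAS3 (0.50) rose of 18 interferon response genes, both with the same counts when adjusted over the list alone (camera adjusted p = 0.758 and 0.188; fry 0.642 and 0.00574). With spike scaling the interferon list passed in camera as higher relative to other genes (adjusted p = 0.0305), with a median of -0.37. That pass is no independent evidence either. At an unadjusted p under 0.05, limma gave 0 p53 targets as higher and 2 as lower, and 4 interferon genes as higher and 0 as lower. BAX and SDHC did not pass without DHT replicate 1, control replicate 1 or control replicate 3, with BAX also lost without DHT replicate 2 and SDHC without DHT replicate 3 (adjusted p = 0.0509 to 0.0791). In the fits with an array left out, UQCRC2, IFIT1, OAS3 and NOLC1 passed in at most 1 (that without DHT replicate 3 for UQCRC2, that without control replicate 3 for IFIT1 and OAS3, and none for NOLC1). UQCRC1 (-0.33), which also fell, did not pass without DHT replicate 3 or any control replicate (adjusted p = 0.0629 to 0.132). UQCRB (-0.31) passed only without control replicate 3 (otherwise adjusted p = 0.0543 to 0.153). Without control replicate 1 none of the 4 respiration falls passed. With the mean of a gene's probe sets, UQCRC2 had -0.03, NOLC1 0.03 and SDHC -0.17 (adjusted p = 0.819, 0.867 and 0.142), and IFIT1 did not pass either (0.98, adjusted p = 0.0547). The control signal of IFIT1, 17.5, lay near the limit of 17.3 on dim probe sets.

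Among markers of other cell types, DDC fell of 7 tested neuroendocrine markers, while CHGA had -0.27 and ENO2 -0.31 without passing. Of 10 fibroblast and smooth muscle markers COL1A1 fell (-0.54), and VIM had 0.32 (adjusted p = 0.093, and 0.0427 without control replicate 3). COL1A1 did not pass without DHT replicate 1, DHT replicate 2, control replicate 1 or control replicate 3 (adjusted p = 0.0521 to 0.0702), nor with the mean of its probe sets (-0.39, adjusted p = 0.0952). Basal prostate markers (5 tested), endothelial markers (5 tested) and leukocyte markers (7 tested) had 0 genes passing in limma, and at an unadjusted p under 0.05 these lists had 1 higher and 1 lower, 0 higher and 1 lower, and 0 higher and 1 lower. When adjusted over the list alone, the counts were 1 fall for neuroendocrine markers, 1 for fibroblast markers, 1 for endothelial markers and 0 for the basal and leukocyte lists. The endothelial receptor TEK had -0.84 (adjusted p = 0.065; 0.0349 without control replicate 2) and the leukocyte gene CD3E had -0.73 (adjusted p = 0.0634; 0.0434 without DHT replicate 2). The camera adjusted p of these 5 lists lay between 0.496 and 0.986. Median and mean log2 fold change had opposite signs for zinc transport (0.03 and -0.02), p53 targets (0.03 and -0.02), basal markers (0.04 and -0.04) and leukocyte markers (0.00 and -0.05).

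**Figure D2:**
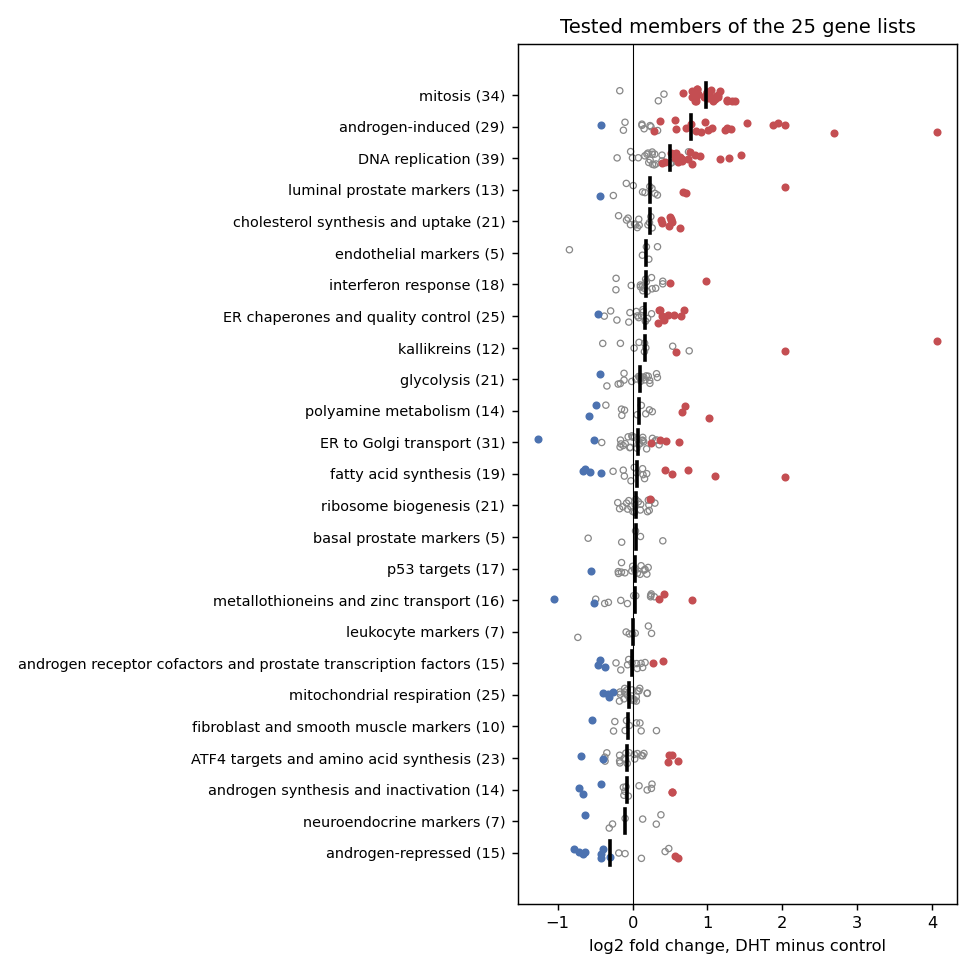
Each point is a tested member of 1 of the 25 gene lists, with its log2 fold change of DHT minus control on the horizontal axis; the number tested stands in brackets and the black bar is the list median. Filled red and blue points passed as higher and lower, open points did not pass. The medians run from 0.99 for mitosis to -0.31 for the androgen-repressed list, and with spike scaling the medians of all lists except mitosis and androgen-induced were negative.

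The control probe sets of the arrays differed with the groups. The hybridisation spikes, bacterial and phage transcripts added to each sample, were brighter with DHT: bioB went from 148 ± 14.4 to 253 ± 28.9, bioC from 469 ± 34.1 to 610 ± 34.6, bioD from 2000 ± 167 to 2523 ± 243 and cre from 5906 ± 557 to 8973 ± 918 (SD, n = 3 each). The ratio of 3' to 5' signal with DHT was 1.30 times that of the controls for ACTB and 1.17 times for GAPDH. For each of these 6 measures all 3 DHT arrays lay above all 3 controls, with an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 arrays allow.

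**Figure D3:**
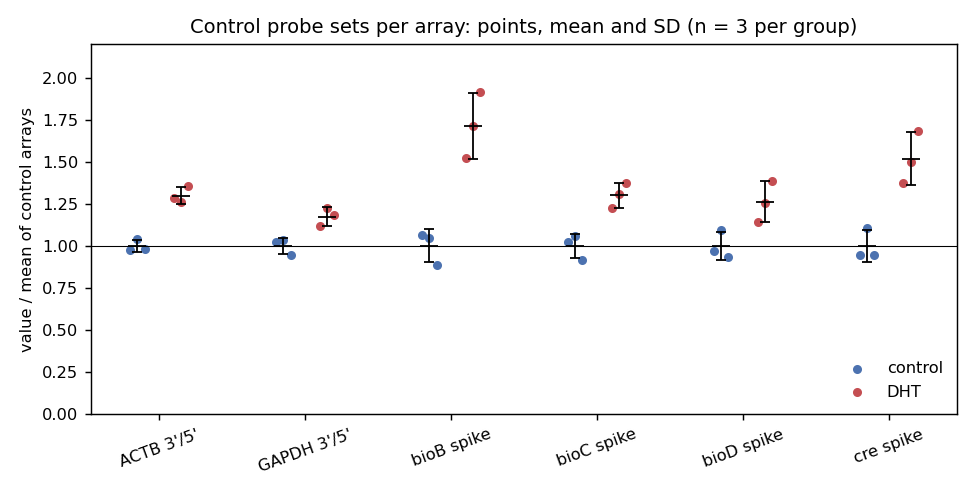
Each point is 1 array, with the value of a control measure divided by the mean of the 3 control arrays on the vertical axis; bars give the mean and SD (n = 3 per group, controls blue, DHT red). The DHT means lie between 1.17 times (GAPDH 3' to 5' ratio) and 1.71 times (bioB) the control mean.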

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

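The tests of a common scaling factor, alone and with a background effect, were chosen after the spike signals were seen. The control probe sets, which enter no gene comparison, differed between the groups. The signal with DHT over that of the controls was 1.71 for bioB, 1.30 for bioC, 1.26 for bioD and 1.52 for cre, and the 3' to 5' ratio was 1.30 times that of the controls for ACTB and 1.17 times for GAPDH, with all 3 DHT arrays above all 3 controls in each.

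One technical explanation is that MAS5 scaling multiplied the DHT arrays by 1 common factor. The log2 ratios of the 4 spikes were 0.78 ± 0.13, 0.38 ± 0.08, 0.33 ± 0.11 and 0.60 ± 0.11 (SE); the difference between bioB and bioD, taken per array, was 0.44 ± 0.07, that between cre and bioD 0.27 ± 0.02, and that between bioC and bioD 0.05 ± 0.05 (SE of the difference, n = 3 arrays per group). A single factor would give 0, so the first differences, 6.48 and 13.0 times their errors, argue against it as the whole cause, although the exact permutation p of both was 0.1, the smallest possible here. A factor with a background subtraction that raises dim spikes more, as the ratio of bioB, the dimmest, would need, leaves cre, the brightest, with the lowest ratio, and its excess over bioD, the next brightest, argues against that too. A scaling factor together with unequal spike addition may still hold and was not tested. Lower RNA integrity or shorter cRNA in the DHT arrays could raise the 3' to 5' ratios, and no other measure of integrity was analysed here. Whether total mRNA per cell changed with DHT was not tested. Hybridisation spikes do not count cells, so the differences between spikes cannot decide it.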

How the results depend on the processing

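The spike scaling was chosen after the data were seen; all other settings were chosen before. Without the variance trend 1264 probe sets and 671 genes passed (384 higher, 287 lower), of which 648 genes were shared with the 1834 and all had the same sign. Scaling to the spikes gave 19958 probe sets and 9245 genes (104 higher, 9141 lower) and 871 genes at 2-fold, with a median log2 fold change of -0.53. It lowered every log2 fold change by the same amount, dim genes included, and so turned 564 of the 991 rises negative. With it 9 lists passed in camera, 6 of them shared with the main 8: cholesterol synthesis and endoplasmic reticulum chaperones no longer passed (adjusted p = 0.121 and 0.780), and ATF4 targets, mitochondrial respiration and interferon response newly did (adjusted p = 0.024, 2.72e-05 and 0.0305). No list's log2 fold changes moved relative to those of other genes. Camera uses fold changes divided by their errors, so these gained and lost calls are no evidence for or against a shift of a list. Of 99 named genes called in the main fit, 67 kept their call, 17 no longer passed and 15 turned sign, and 22 others newly passed. The totals below leave the spike scaling out. With equal medians 644 genes were higher. At least 2-fold changes numbered 228 with a pseudocount of 1, 48 with 64 and 93 with the mean of a gene's probe sets, the pseudocount acting on dim genes by construction. HMGCS1 reversed to -0.0637 with that mean, since its probe sets oppose each other. Camera with an estimated correlation gave 0 lists (5 at an unadjusted p under 0.05), and fry 10 of 25. The estimated-correlation test also has only 4 degrees of freedom. For kallikreins, luminal markers and endoplasmic reticulum chaperones the estimated correlation was -0.002, 0.010 and 0.011. Their unadjusted camera p still rose from 0.0011, 0.0020 and 0.00064 to 0.026, 0.037 and 0.028. Correlation alone therefore did not remove these lists. With an array left out, 2064 to 2644 probe sets, 1168 to 1405 genes, 624 to 779 higher and 513 to 658 lower genes passed, with fewer arrays in the fit. The lowest gene counts were 1168 without control replicate 3 and 1178 without DHT replicate 3, and 652 were higher without DHT replicate 2. Same-numbered arrays deviated from their group means with r = -0.01, -0.03 and -0.00, so no pairing by number was visible. With 3 arrays per group this cannot exclude a shared day. The fit with the replicate block gave 3114 probe sets and 1698 genes. UQCRC2, UQCRB, PIAS1 and NOLC1 were not among them (adjusted p = 0.0505, 0.0557, 0.0594 and 0.0771), and PFKP newly passed as lower (adjusted p = 0.0382). Of 815 values of named genes with an array left out 726 kept direction and side of the threshold, 82 no longer passed and 7 newly passed; of 1355 under other settings apart from the spike scaling 1270 kept both, 80 no longer passed, 4 newly passed and 1 reversed. With camera's preset correlation, 249 of 250 list values under settings other than the spike scaling and 149 of 150 with an array left out kept their call; mitochondrial respiration newly passed under quantile normalisation (adjusted p = 0.025) and without control replicate 3 (adjusted p = 0.016). The cause of the other changes was not tested. Signal near background limits calls of dim genes such as TRPM8 and MINK1.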

Other observations

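The genes in this paragraph were chosen after their values were seen. Outside the lists, ALDH1A3, which makes retinoic acid from retinal, rose 3.03-fold with DHT from a signal of 136 ± 12.4 to 410 ± 28.8 (SD, n = 3 each). The bicarbonate cotransporter SLC4A4 rose 2.72-fold from 550 ± 45.1 to 1496 ± 98.2, and the potassium channel KCNMA1 rose 2.72-fold from 128 ± 23.1 to 347 ± 63.8. CTBP1, a transcriptional corepressor, had a log2 fold change of -1.13 ± 0.10 (1421 ± 31.5 to 644 ± 97.2), and its antisense transcript CTBP1-AS had 1.68 ± 0.22, from 4.85 ± 1.51 in the controls, below the limit on dim probe sets, to 51.3 ± 9.34. The noncoding RNA MIR210HG dropped from 53.3 ± 3.39 to 8.35 ± 0.31, below that limit too. Of the 98 genes at least 2-fold higher, 32 were in a list, 18 of them for DNA replication or mitosis and 11 androgen-induced, while 2 of the 46 at least 2-fold lower genes were in one.

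The next tests were fixed before their results were seen. If the falls came from the signal of single probe sets, a gene's second brightest probe set would go the same way in under 65% of the genes, and otherwise in over 85%. It did so for 74.0% of the 435 fallen genes with one (95% exact interval 69.6 to 78.1) and for 77.3% of 596 risen genes (73.8 to 80.7), against 47.7% going up among genes that did not pass. For changes of at least 2-fold the share was 100% of 15 falls (78.2 to 100) and 88.5% of 52 rises (76.6 to 95.6). The intervals for all falls and all rises lie between both bounds and those for 2-fold changes span 85%, so a contribution of single probe sets to these changes may remain. Fisher's exact test of falls against rises gave p = 0.238.

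The same test on the risen DNA replication and mitosis genes gave 100% of 23 (85.2 to 100), which argues against single probe sets as the source of that pattern. The estimated correlation between genes was 0.488 in the mitosis list and 0.275 in the replication list. With it, and with the 4 degrees of freedom of that test, neither list passed in camera (adjusted p = 0.190 and 0.269). The highest absolute list median over the other 9 splits of the arrays was 0.57 for mitosis and 0.29 for DNA replication, against 0.99 and 0.50 for the real split. Those splits mix both treatments in each group and keep part of the DHT difference, so none is a null. Among the other lists that passed in camera, another split gave a larger median for kallikreins (0.18 against 0.17) and luminal markers (0.24 against 0.23). More cycling cells with DHT is a hypothesis that may account for the rise, and cell counts were not analysed here.

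The 10 splits of 6 arrays into groups of 3 are too few for a share under 0.05. Each split other than the real one mixes both treatments in both groups. The DHT effect then adds to the spread within groups, and part of it stays between them. Such splits are no null, and their counts do not give the rate of calls without an effect. The real split gave 3388 probe sets, 1834 genes and 144 genes at 2-fold, and the highest of the other splits 0 for each, so that 1 of the 10 splits gave as many. At an unadjusted p under 0.05, limma gave 3701 genes for the real split and at most 558 genes for the others. The real split gave 8 lists and the others at most 6, again 1 of 10. Families of genes that share the letters of their symbol, a test chosen after the other results were seen, gave 3 families in the real split and up to 5 in others. They were KIF, MCM and NUP (medians 0.30, 0.30 and 0.24, camera adjusted p = 0.0464 each, and 0.97 with an estimated correlation). As many came from 3 of the 10 splits, which are no null, so this count weighs neither for nor against these families. Several KIF and MCM genes are also in the mitosis and DNA replication lists, so these 2 families are not separate from that pattern.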
